A study of Mus musculus with 4 samples.

How the data were processed

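Uterine RNA of female C57/B6 mice was measured on Affymetrix MG_U74Av2 arrays, on which sets of short oligonucleotide probes (probe sets) each target a transcript. The mice had been ovariectomized, primed with steroid hormones and given oil to induce decidualization, the differentiation of the uterine stroma, and progesterone was then withdrawn, per the labels. RNA of 4 animals was pooled for each of 4 times, 36, 48, 60 and 84 h after the last progesterone injection, and each pool was hybridized to 1 array, so that every time has 1 value per gene and no replicate. Per the labels' protocols, RNA came from 1 uterine horn of each animal.

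The deposited values were intensities on a linear scale, 1 signal per probe set, made with MAS5 per the submitters' processing notes; the version of that software was not given in the sources used here. The deposited intensities were already scaled by the authors, since the mean of the central values, after leaving out the lowest and highest 2% of probe sets, was 100.1 on each of the 4 arrays. They were therefore used as deposited, and no detection calls were used here. The scanner's deposited experiment records hold no signal and were read only for the conditions of hybridization: the 4 arrays shared 1 chip lot, 1 fluidics station, 1 protocol, 1 hybridization day and 1 scan day, but each ran on its own of 4 fluidics modules, so module and time cannot be told apart. Such records say nothing of the day on which tissue was taken.

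Of 12488 probe sets, 66 were controls and were used only for quality. Among the other 12422, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none; only those with 1 symbol were named. Entrez identifiers of 10817 of the 10833 were found in the RefSeq gene table of assembly GRCm38.p6, which was used only for names and changed no symbol. No genome build was named for the arrays, so no coordinates are given. Each of 8251 genes was represented by its brightest probe set over the 4 arrays.

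Signals under the 40th percentile of all values, 26.4, were set to that floor. A gene was compared between 2 arrays only if the higher one lay above the floor, and a ratio whose lower array lay at the floor is a bound, written "at least". Genes at least 2-fold apart were counted. A gene is called uncertain where its probe set carries a suffix that marks shared or imperfect probes (_f, _s, _r, _i or _g) or where another probe set of the gene went the opposite way. With 1 array per time no test between 2 times was possible, no trend over the hours was fitted, and the differences have no replicate check: they describe these 4 pools. The number of arrays limits the precision.

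Part of the technical error was estimated from 872 genes with a pair of probe sets above the floor on average. The estimate was the SD of the difference in log2 ratio between them divided by the square root of 2. It was 0.29 for 48 h over 36 h, 0.29 for 60 h over 36 h, 0.33 for 84 h over 36 h, 0.27 for 60 h over 48 h and 0.34 for 84 h over 60 h. It holds no variation between animals. Errors of RNA preparation, labelling or hybridization that both probe sets of a gene share cancel in it, so it is not the full error between arrays. The differences between probe sets were also drawn at random for every gene, 100 times, to see how many genes would pass 2-fold from them alone. The draws reuse the same 872 pairs, so the ranges over draws do not show how well these pairs stand for other genes. Genes near the floor are less well covered by them.

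Before the data were examined, 29 gene lists were fixed: decidual stroma, progesterone-regulated and oestrogen-regulated uterine genes, matrix metalloproteinases and other matrix proteases, protease inhibitors, structural extracellular matrix, neutrophil, macrophage and monocyte, natural killer cell, T cell, B cell and plasma cell, mast cell, inflammatory cytokines with chemokines and adhesion molecules, endothelial, angiogenic factors, hypoxia and glycolysis, cell cycle, epithelial, smooth muscle, apoptosis, prostaglandin synthesis and receptors, TGF-beta with BMP and WNT signalling, interferon-responsive, erythroid and haemoglobin, platelet and coagulation, immediate early genes, adipose tissue, skeletal muscle, and housekeeping. Some genes, such as Lcn2 and Ltf, stand in several lists. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and the list is said to stand apart where it lay at or beyond percentile 2.5 or 97.5. This percentile compares genes on the same arrays and does not say whether a second pool of animals would behave alike.

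Genes named were those fixed by a rule before the data were examined: for each time against 36 h, the 12 largest ratios in each direction with both arrays above the floor plus the 4 brightest bounds; for 60 h over 48 h and 84 h over 60 h, the 6 largest in each direction; and the 4 members of each list with the largest range. Not all of them are printed. Other members of the lists that are named were chosen after their values were seen.

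The counting and list methods were tested on simulated data made from the real gene means and the probe set SD of 84 h over 36 h. Changes were planted only in genes with a mean signal over 4 times the floor, so recovery nearer the floor was not tested. Of 100 genes planted 2-fold apart 42% passed the 2-fold rule in the right direction, and of 100 planted 4-fold apart 100% did. Of the unchanged genes 13 passed among 5875 compared, and 4.5% of 200 random lists fell outside the percentiles 2.5 to 97.5. The simulated noise was normally distributed. The observed probe set differences, drawn at random, gave a median of 55 genes past 2-fold for 84 h over 36 h, so the 13 may understate false calls.

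Alternatives fixed before the data were examined were quantile normalization, scaling by the median or by the trimmed mean, floors at the 25th and 60th percentile, no floor with a pseudocount of 16, the mean of a gene's probe sets, leaving out suffixed probe sets, and a 3-fold threshold. Scaling to the 9 hybridization spike-in probe sets, leaving out the members of the adipose, erythroid and B cell lists, and leaving out the 84 h array were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.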

Results

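Gene expression was followed in the uterus of a mouse model of menstruation, in which decidualized tissue is deprived of progesterone. The 4 arrays were 1 pool of 4 animals each at 36, 48, 60 and 84 h after the last progesterone injection. On them 5763, 5763, 5683 and 5766 genes lay above the floor. These numbers are similar in part by construction, since the arrays were scaled to the same mean and share 1 floor. Log2 signals correlated across 6138 genes with Pearson's r between 0.958 and 0.980, the lowest value being that of 36 h and 84 h; genes are not independent replicates. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, was 1.28, 1.28, 1.47 and 1.76 in time order, whereas that of Gapdh was 0.976, 0.998, 1.03 and 0.983 and that of pyruvate carboxylase 2.72, 4.32, 2.90 and 3.65. Hybridization spike-ins were 1.09-fold, 0.927-fold and 1.36-fold the 36 h level at 48, 60 and 84 h. No animals kept on progesterone were analysed here, so each later time was set against 36 h, and time and withdrawal cannot be separated. Every count of genes past 2-fold moved by over 1.5 times with the floor: for 84 h over 36 h, 163 genes were higher and 190 lower with the floor at the 25th percentile, and 43 and 50 with it at the 60th.

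At 48 h, compared with 36 h, 1 of 7 natural killer, 3 of 17 progesterone-regulated and 1 of 28 cell cycle genes were at least 2-fold lower. A few myeloid genes were at least 2-fold higher, 2 of 11 neutrophil and 1 of 20 macrophage genes, but neither list stood apart (percentiles 91.1 and 58.2). Gzmb, the cytotoxic protease granzyme B, was 2.87-fold lower (196.2 to 68.3 intensity units), and Acod1, which makes itaconate and is induced by progesterone in the uterus, was 4.11-fold lower (176.5 to 42.9, uncertain). Guca2b, the peptide uroguanylin, was at least 7.38-fold lower and Alox15, a lipoxygenase, 2.37-fold lower. Higher were Arg1, the enzyme arginase 1, by 2.54-fold (179.4 to 455.8), S100a8, a calcium-binding protein of neutrophils, by 2.52-fold, Mmp12, the macrophage elastase, by 2.68-fold (uncertain, although its other probe set was at least 2.73-fold higher), and Aldh1a2, an enzyme of retinoic acid synthesis, by 2.36-fold.

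In all, 22 genes were at least 2-fold higher and 39 at least 2-fold lower at 48 h among 5977 compared, of which 5 and 10 were bounds. The natural killer cell list lay lowest: 7 of 7 compared members were below 0, 1 at least 2-fold, with a median of -0.63 on the log2 scale (percentile 0), 2 of the 7 being bounds. Of 17 progesterone-regulated genes 3 were at least 2-fold lower and none higher, with a median of -0.24 (percentile 0.095): besides Acod1 they were Cyp26a1, a retinoic acid hydroxylase, 2.23-fold lower, and Per1, which is also a clock gene, 2.16-fold lower. The smooth muscle list had a median of -0.16 (percentile 0.46; 11 of 14 members below 0), the cell cycle list -0.17 (0.25; 21 of 28 below 0, with Mki67 2.03-fold lower), the structural matrix list -0.08 (0.72) and the B cell list -0.26 (1.97). Only the immediate early list stood apart upward, with a median of 0.26 (99.9; 13 of 18 above 0, none by 2-fold). Further genes at least 2-fold higher were Dbp (2.42-fold) and Nr1d2 (2.19-fold), transcription factors of the circadian clock, Adamdec1 (2.61-fold), a metalloprotease, and Hand1 (2.13-fold), and S100a9, the partner of S100a8, was at least 2.33-fold higher. Further lower genes were Npl (2.86-fold), Dcaf12 (2.64-fold), Napsa (2.47-fold), an aspartic protease, Tspan13 (2.47-fold) and Slc25a10 (2.45-fold), a mitochondrial dicarboxylate carrier, while Tac2, which encodes neurokinin B, and Hsd11b1, which regenerates active glucocorticoid, were at least 2.82-fold and 2.80-fold lower.

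Probe set differences alone gave a median of 48 genes past 2-fold (34 to 72 over 100 draws), against 22 higher and 39 lower at 48 h, so that their number cannot be told from technical error. The largest ratio with both arrays above the floor, a 5.17-fold lower signal of Actb (517.9 to 100.2, uncertain), was not matched by the actin control probe set, 1.20-fold higher (4677 to 5608), while another actin probe set was 1.75-fold lower (265.5 to 151.5). With a pseudocount in place of the floor the natural killer median was -0.20, and with spike-in scaling 15 genes were higher and 64 lower.

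**Figure D1:**
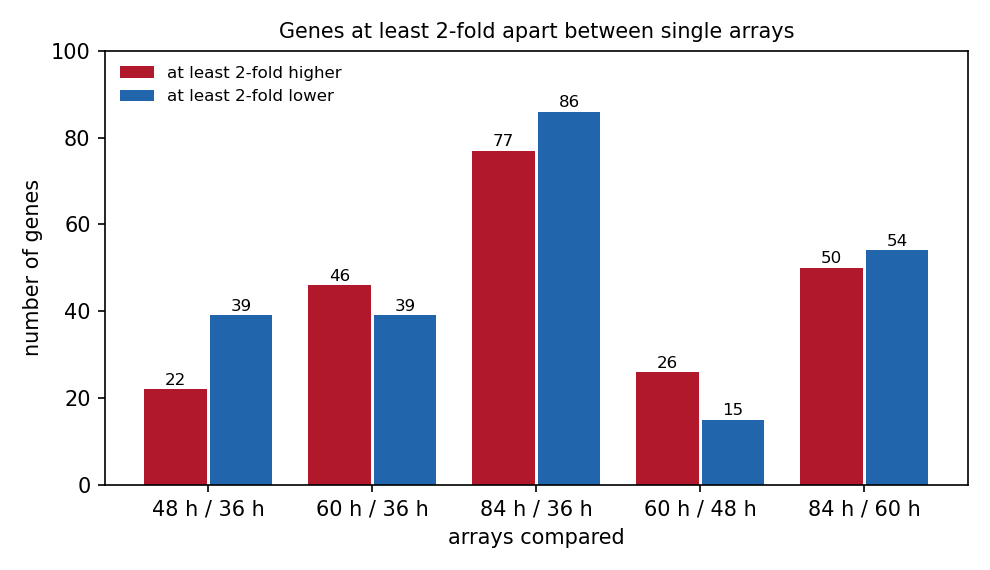
Number of genes (y axis) at least 2-fold higher (red) or lower (blue) in the first array of each pair than in the second (x axis); each array is 1 pool, so bars carry no error. The counts reach 77 and 86 genes for 84 h over 36 h, against 22 and 39 for 48 h over 36 h.

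At 60 h, compared with 36 h, some genes of neutrophils and of inflammation were higher. S100a8 was 6.03-fold higher (48.4 to 291.8) and S100a9 at least 5.34-fold, and the neutrophil-attracting chemokines Cxcl5 and Cxcl1 were 4.49-fold and at least 3.95-fold higher. Il1b, the cytokine interleukin 1 beta, was at least 4.20-fold higher (4.3 to 110.8). Saa3, an acute phase protein, was 6.18-fold higher (180.8 to 1118), Chil3, a chitinase-like protein of macrophages, 4.41-fold, and Arg1 3.22-fold. Of the matrix proteases, Mmp12 was 7.38-fold higher (44.1 to 325.6, uncertain; its other probe set was at least 3.10-fold higher) and Mmp7, matrilysin, 3.39-fold higher (167.1 to 566.2).

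Of 5921 genes compared, 46 were at least 2-fold higher and 39 at least 2-fold lower, 8 and 9 of them as bounds. Of 12 neutrophil genes 4 were at least 2-fold higher and none lower, with a median of 0.64 (percentile 100): S100a8, S100a9, Il1b and Clec4d, a lectin receptor, at least 2.22-fold. Of the 12, 8 were above 0 and 5 were bounds. S100a9, Il1b, Clec4d and Prtn3 lay under the floor at 36 h, so they could only come out higher. The others above 0 were S100a8, Lcn2, Mmp9 and Pglyrp1. The 4 below 0 were Ltf, 1.53-fold lower, Csf3r, 1.34-fold, Elane, 1.25-fold, and Camp, 1.11-fold lower. Of 20 list members on the array only these 12 passed the floor on any array, and Ngp, Mpo, Ly6g and Cxcr2 were among those that did not. Lcn2, a secreted iron-scavenging protein that neutrophils and epithelium make, was 1.95-fold higher. Of 22 inflammatory genes 7 were at least 2-fold higher and none lower, with a median of 0.37 (percentile 100). Among those higher were Ccl2, the monocyte chemokine, by 2.23-fold, Ccl9 by 2.37-fold, Cxcl14 by 2.24-fold and the adhesion molecule Vcam1 by 2.12-fold. Of the 22, 7 were bounds, Il1b and Cxcl1 among them. The macrophage list had a median of 0.24 (percentile 99.95) with 16 of 22 members above 0, but only Chil3 and Arg1 passed 2-fold. Wnt4, a signal of decidualization, was 3.13-fold higher (34.1 to 106.7) and Tgfb1 2.53-fold higher, while the list of TGF-beta, BMP and WNT signalling as a whole did not stand apart (median 0.05, percentile 82.5). Nor did the decidual stroma list (median -0.10, percentile 17.1), in which 9 of 14 members were below 0 and only Wnt4 passed 2-fold.

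The lists that stood apart downward at 60 h were the oestrogen-regulated genes (median -0.46, percentile 0), the natural killer list (-0.60, percentile 0.020), the progesterone-regulated genes (-0.29, 0.020; 14 of 17 below 0, 1 by 2-fold), smooth muscle (-0.28, 0.020; 13 of 14 below 0), structural matrix (-0.17, 0.020; 24 of 30 below 0 and none by 2-fold), prostaglandin synthesis and receptors (-0.33, 0.14; 12 of 13 below 0), epithelial (-0.12, 2.42) and skeletal muscle (-0.30, 1.71). Igf1, the insulin-like growth factor 1 that oestrogen induces in the uterus, was 2.55-fold lower (442.9 to 174, uncertain) and Sprr2f, a cornified envelope protein of the epithelium, 2.70-fold lower (1155 to 427.7, uncertain). Smtn, the smooth muscle protein smoothelin, was 2.12-fold lower. Alox15 was 2.01-fold lower, Gzmb 3.63-fold, Inmt, a methyltransferase, 2.47-fold and A2m, the protease inhibitor alpha 2 macroglobulin, 2.59-fold lower.

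Probe set differences alone gave a median of 14 genes past 2-fold (5 to 25), fewer than were counted. For 48 h over 36 h, with the same SD of 0.29, they gave 48, so such numbers depend on the pairs with the largest differences. The neutrophil median was 0.26 and the natural killer median -0.16 with a pseudocount in place of the floor, and spike-in scaling gave 65 genes higher and 32 lower.

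At 84 h, compared with 36 h, some genes typical of fat and of red blood cells were higher, and some genes of the progesterone response, of smooth muscle and of the epithelium were lower. Car3, a carbonic anhydrase abundant in adipocytes, was 32.4-fold higher (27.6 to 893.5), and Adipoq, adiponectin, and Retn, resistin, both secreted by adipocytes, were at least 22.9-fold and at least 9.60-fold higher. Hba-a1, alpha globin, was 9.42-fold higher (418.7 to 3946), and Alas2, the erythroid enzyme of haem synthesis, at least 4.91-fold (uncertain). Acod1 was 6.07-fold lower (uncertain), Cyp26a1 3.85-fold (160.1 to 41.6) and Lrp2, the endocytic receptor megalin, 3.29-fold lower.

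Of 5994 genes compared, 77 were at least 2-fold higher and 86 at least 2-fold lower, 12 and 15 of them as bounds. Of 17 progesterone-regulated genes 7 were at least 2-fold lower and 1 higher, with a median of -0.75 (percentile 0) and 5 members above 0. The transcription factor Zbtb16 was at least 3.97-fold lower (uncertain), Hdc, which makes histamine, 2.37-fold lower (916.2 to 387), Per1 2.34-fold and Errfi1 2.15-fold lower, whereas Pgr, the progesterone receptor, was 2.65-fold higher (36.3 to 96.2). The smooth muscle list had a median of -0.53 (percentile 0) with 13 of 14 members below 0, Smtn 2.48-fold and the smooth muscle actin Actg2 2.12-fold lower (uncertain). Of 22 epithelial genes 4 were at least 2-fold lower and none higher (median -0.27, percentile 0.070): Ovgp1, a secreted glycoprotein, by 3.73-fold, the tight junction genes Cldn3 and Cldn4 by 2.70-fold and 2.52-fold, and Lcn2 by 2.04-fold (uncertain). The natural killer list again lay low (-0.63, percentile 0.030), as did mast cell (-0.35, 1.70; -0.68 with the lower floor), in which Hdc was the member past 2-fold, decidual stroma (-0.23, 1.70), prostaglandin (-0.25, 1.60), interferon-responsive (-0.21, 1.05; no member by 2-fold) and skeletal muscle genes (-0.32, 1.42). The natural killer median at both 48 and 84 h over 36 h was the ratio of Gzmd (uncertain), which lay below the floor at both times. The repeated -0.63 is therefore set by the floor, and 3 of the 7 members compared at 84 h were bounds. Prl8a2 and Prl3c1, prolactin family genes that the decidua expresses, were below the floor on all 4 arrays.

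Among the genes with the largest ratios, F2r, the thrombin receptor PAR1, was 4.53-fold lower (610.4 to 134.7) with both of its other probe sets in the same direction, Ramp1, a subunit of the CGRP receptor, 3.67-fold lower, Ltf, lactoferrin, 3.64-fold lower (1039 to 285.4), and Slc39a4, a zinc importer, 3.61-fold lower. Inmt was 4.31-fold lower and the thioesterase Acot7 3.47-fold lower. Higher were Mmp12 by 15.9-fold (44.1 to 702.2, uncertain; its other probe set was at least 4.34-fold higher), Saa3 by 6.64-fold, A2m by 5.78-fold and Hp, haptoglobin, by 5.99-fold, the chaperone Hspa5 by 3.25-fold, Scd1, a fatty acid desaturase, by 6.84-fold and Cyp2e1 by 7.58-fold.

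Of 10 adipose tissue genes 5 were at least 2-fold higher at 84 h and none lower, with a median of 0.76 (percentile 100): besides Car3, Adipoq and Retn these were Lpl, lipoprotein lipase, by 3.75-fold, and Fabp4, the adipocyte fatty acid-binding protein, by at least 2.10-fold (11.6 to 55.5). With the floor at the 25th and the 60th percentile that median was 1.31 and 1.91, and relative to the median gene it was 1.17 with spike-in scaling. Pnpla2, Lipe and Lep differed by 1.08-fold, 1.36-fold and 1.01-fold. The erythroid list had a median of 0.42 (percentile 99.5) with Hba-a1 and Alas2 the 2 of 6 members past 2-fold (0.79 with the higher floor), and Hbb-b2, a beta globin outside the list, was 6.08-fold higher. The B cell list had a median of 0.24 (percentile 97.6), with 7 of 10 members above 0. Of the 10, 3 were at the floor at 36 h and could only come out higher. Ighm, the immunoglobulin heavy chain mu, was 3.79-fold higher (283.3 to 1074, uncertain, with all 4 of its other probe sets higher too) and Jchain 2.04-fold. The macrophage list (0.24, percentile 99.6) and the inflammatory list (0.33, percentile 99.9, with Ccl9 3.21-fold higher) also stood apart upward. The neutrophil list did not (0.24, percentile 96.8). Of 20 macrophage genes only 12 were above 0, with Arg1 2.21-fold higher and Aif1 2.34-fold lower the members past 2-fold. Oestrogen-regulated genes had a median of 0.08 (percentile 81.1; 2 members at least 2-fold higher and 5 lower), which was -0.49 with the higher floor. Structural matrix genes had a median of -0.08 (percentile 7.52) and endothelial genes of -0.02 (percentile 44.0).

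The 84 h array also had the highest actin 3' to 5' ratio (1.76) and spike-in signal, which stands beside every difference of this time. Scaling to the spike-ins moved the median log2 ratio of all genes to -0.42 and gave 20 genes higher and 360 lower, and probe set differences alone gave a median of 55 genes (44 to 73), fewer than were counted.

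**Figure D2:**
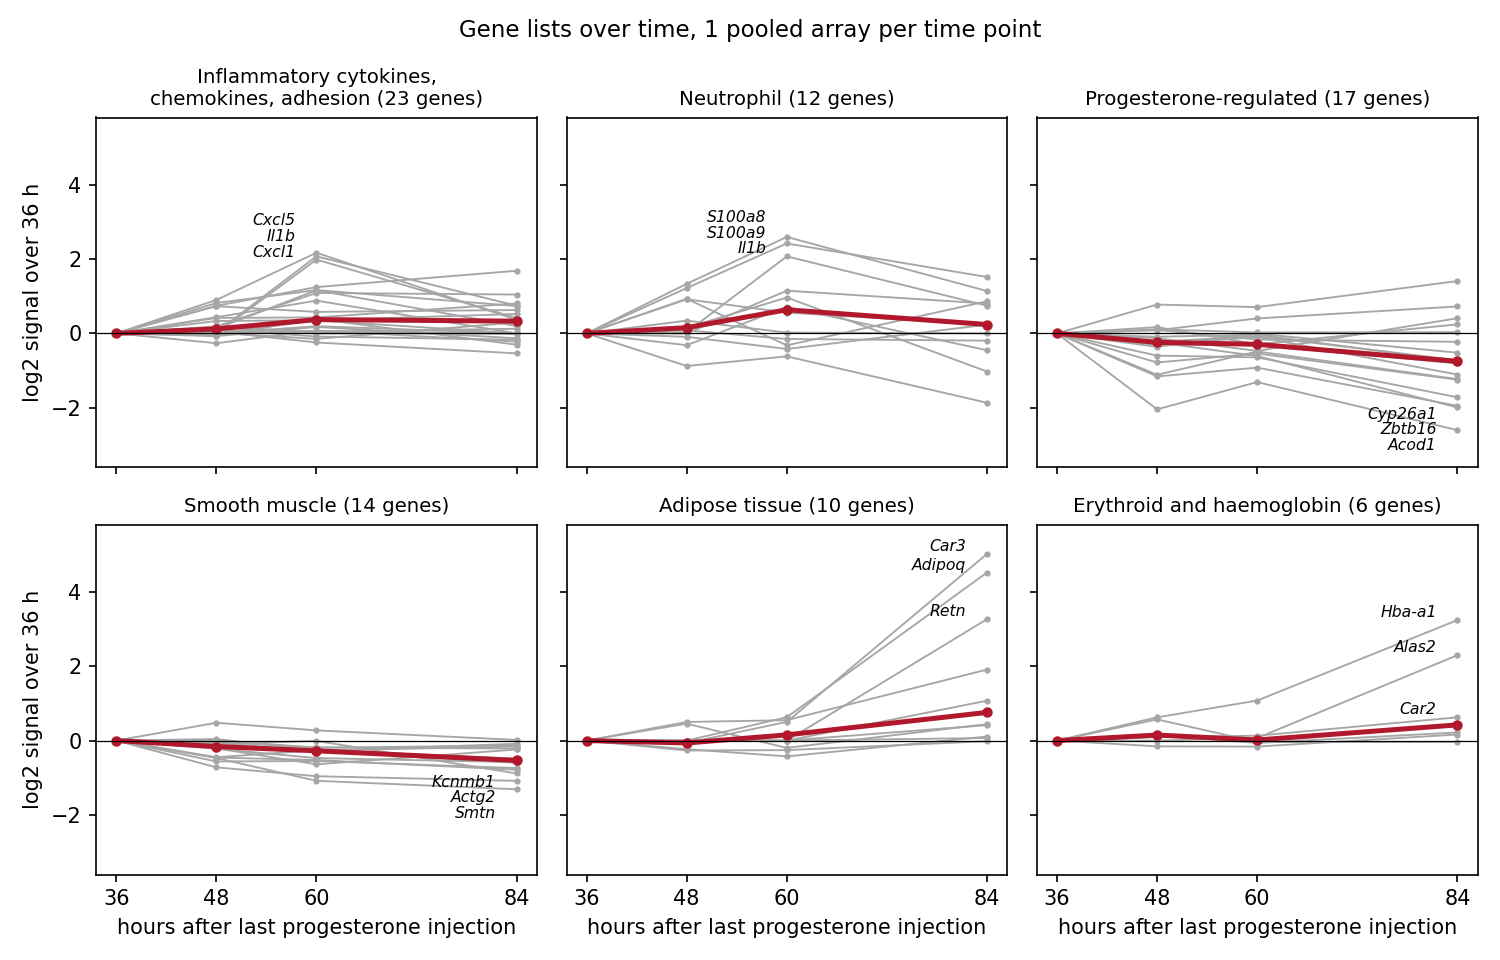
Log2 signal over that at 36 h (y axis) against hours after the last progesterone injection (x axis) for members of 6 gene lists above the floor on any array; grey lines are genes, with the 3 of largest change named, and the red line is the median of the members compared at each time, with 1 pool per time. The neutrophil median is highest at 60 h (0.64) and the adipose median at 84 h (0.76), while the progesterone-regulated median is lowest at 84 h (-0.75).

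Between 48 and 60 h the differences were fewer, and some inflammatory genes were higher, 4 of 23 list members by at least 2-fold. Il1b was 4.10-fold higher at 60 h (27 to 110.8), Saa3 3.24-fold and Mmp12 2.75-fold (uncertain), and Gjb2, a gap junction protein, was 2.47-fold higher. Khdrbs1 was 2.53-fold higher. Nit1 was 2.85-fold lower, Snrp1c-ps2 2.78-fold (uncertain), Arfgap2 2.47-fold, Dbp 2.31-fold, A2m 2.24-fold and Inmt 2.16-fold lower. In all, 26 genes were at least 2-fold higher and 15 lower among 5922, 8 and 9 of them as bounds, against a median of 13 (9 to 23) from probe set differences alone. The neutrophil (median 0.53, percentile 100), macrophage (0.27, 100) and inflammatory lists (0.25, 100) stood apart upward, as did cell cycle (0.15, 99.6) and interferon-responsive genes (0.14, 99.2). Smooth muscle (-0.20, 0.010), oestrogen-regulated (-0.15, 1.29) and structural matrix genes (-0.08, 1.41) stood apart downward. The neutrophil median was 0.036 with the lower floor and 0.034 with a pseudocount, and spike-in scaling gave 66 genes higher and 11 lower.

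Between 60 and 84 h some inflammatory genes were lower and some genes of fat and blood higher: of 22 inflammatory genes 3 were at least 2-fold lower and 6 were above 0, and 5 of 10 adipose and 2 of 5 erythroid genes were at least 2-fold higher. Lcn2 was 3.97-fold lower at 84 h (uncertain), Chil3 3.65-fold, Cxcl5 3.49-fold, Cxcl1 2.96-fold and S100a8 2.74-fold lower, and Mmp7 was 2.17-fold and Mmp11, stromelysin 3, 2.63-fold lower. Car3 was 22.9-fold, Adipoq 14.8-fold, Scd1 7.48-fold and Ighm 5.28-fold higher (the last uncertain), and A2m was at 637.1 against 42.6. Of 5942 genes, 50 were at least 2-fold higher and 54 lower, 11 and 12 of them as bounds.

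In this interval the neutrophil (-0.62, percentile 0; -0.25 with a pseudocount), progesterone-regulated (-0.64, 0), inflammatory (-0.24, 0.040), decidual (-0.31, 0.11), matrix protease (-0.32, 0.12), interferon-responsive (-0.18, 1.34) and epithelial lists (-0.18, 2.10) stood apart downward. The adipose (0.86, 100, and 1.36 with the higher floor), oestrogen-regulated (0.34, 100), erythroid (0.49, 99.6) and B cell lists (0.30, 99.0, with 5 of 10 members bounds) stood apart upward. So did the cell cycle (0.19, 98.6), housekeeping (0.20, 98.3) and structural matrix lists (0.13, 98.2). Of the oestrogen-regulated genes, Ramp3 was 3.26-fold and Aqp8, a water channel, 2.51-fold higher, but Lcn2 and Ltf were lower, and with the higher floor the median of this list was -0.023 and that of the progesterone-regulated list -0.10. Probe set differences alone gave a median of 89 genes past 2-fold (58 to 114), a range that holds the number counted; median scaling gave 44 higher and 73 lower and spike-in scaling 15 and 529.

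**Figure D3:**
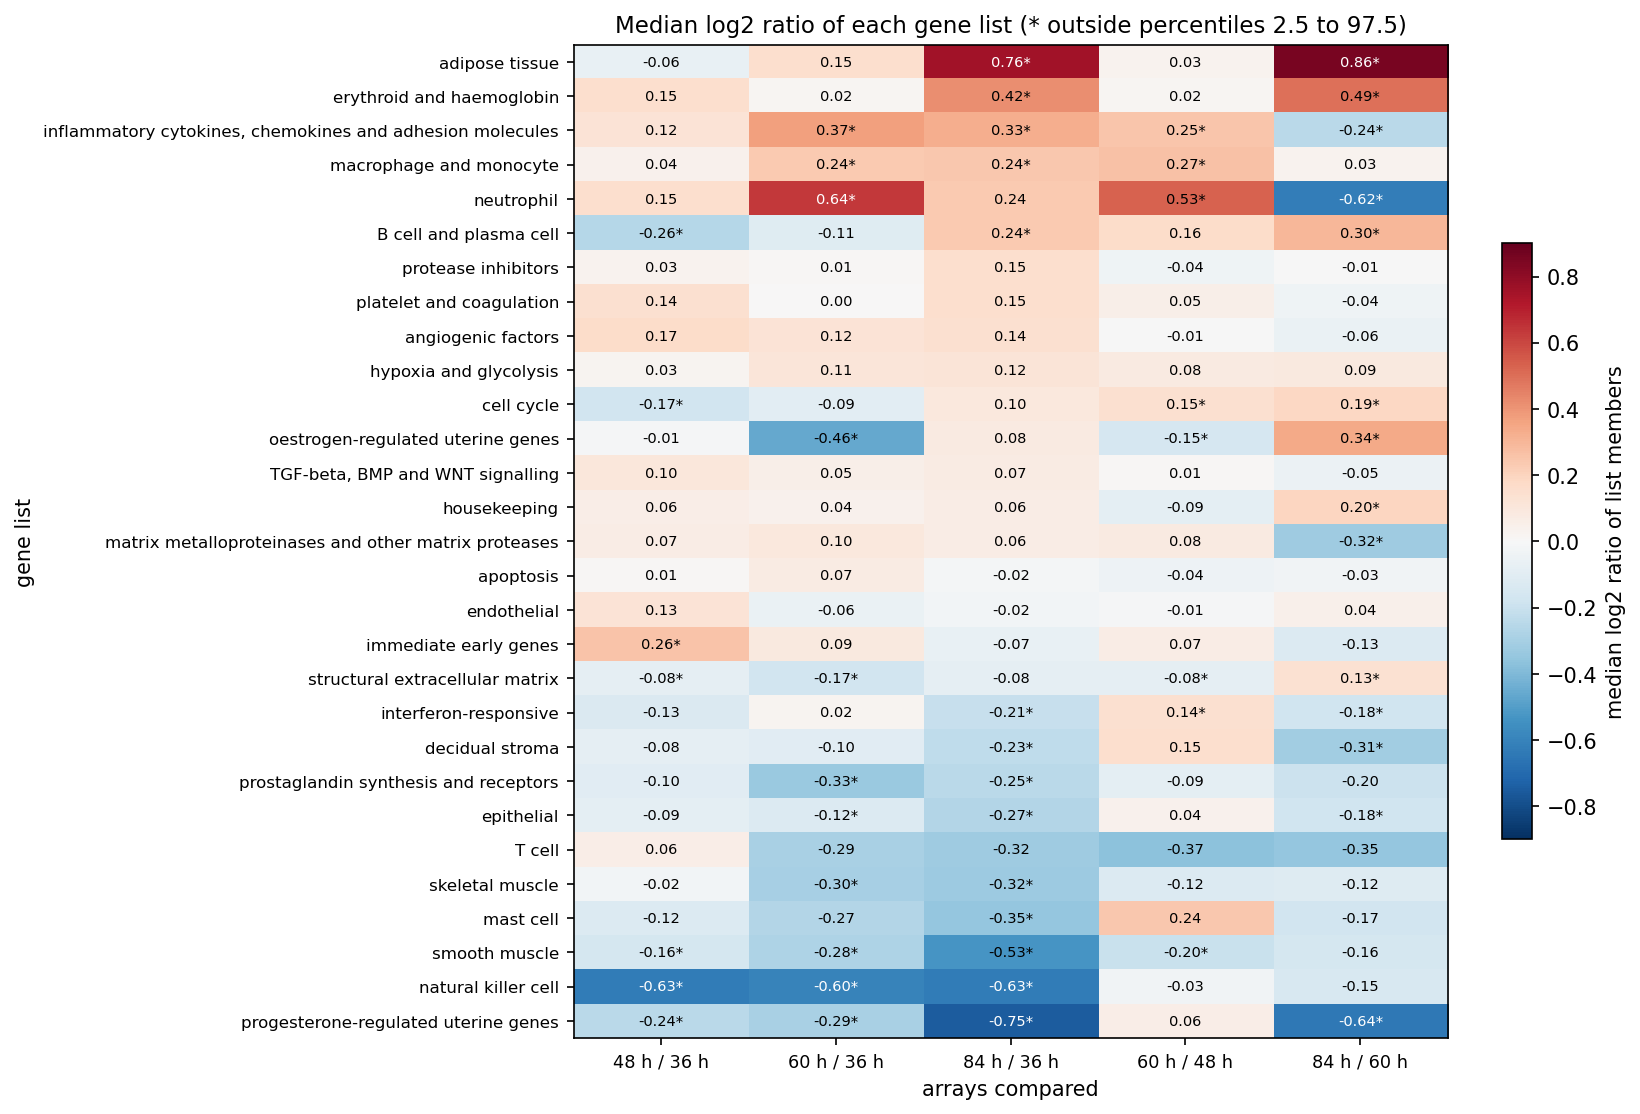
Median log2 ratio (colour and printed value) of the members of each of 29 gene lists (y axis) for 5 pairs of arrays (x axis, first array over second); an asterisk marks lists that stood apart from 10000 matched random lists. Progesterone-regulated genes have the lowest median for 84 h over 36 h (-0.75) and adipose tissue genes the highest (0.76).

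Over the whole course 312 genes varied at least 2-fold. Most of them had their highest signal at an end of the series: 106 at 36 h and 109 at 84 h, against 39 at 48 h and 58 at 60 h. S100a8, S100a9, Il1b, Cxcl1, Cxcl5, Chil3, Arg1 and Mmp7 were highest at 60 h. Mmp12 was higher at each step, as were 33 genes in all, and 37 genes were lower at each step, Inmt and Ramp1 among them. With spike-in scaling the numbers were 291, 65, 458 and 25 at 36, 48, 60 and 84 h, so that which time held most of the highest signals depends on the scaling. Without the 84 h array 61 genes were highest at 36 h and 23 at 48 h.

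Genes at least 2-fold from 36 h at both 60 and 84 h numbered 16 higher and 20 lower, where independent lists would share 0.561 and 0.572 and probe set differences with the same 36 h deviation gave a median of 0 and a maximum of 0. Those shared by 48 and 60 h numbered 9 and 13 (0.154 and 0.260 if independent; a median of 3 and at most 9 from probe set differences in each direction), and those shared by 48 and 84 h numbered 6 and 17 (0.258 and 0.572; a median of 3, at most 11 higher and 7 lower). All of these ratios use the 36 h array, and part of the excess may come from it. Every draw reused the same 872 gene pairs, so the maximum of 0 for 60 and 84 h does not exclude technical error.

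Several lists stood apart in no comparison. The angiogenic factors had medians of 0.17, 0.12 and 0.14 at 48, 60 and 84 h over 36 h (percentiles 94.8, 91.3 and 88.6), hypoxia and glycolysis genes of 0.03, 0.11 and 0.12 (51.9, 93.7 and 89.0), although the haem-degrading enzyme Hmox1 was 2.15-fold higher at 60 h, and protease inhibitors of 0.03, 0.01 and 0.15 (52.1, 46.8 and 92.4). Medians of apoptosis genes were 0.01, 0.07 and -0.02 (52.5, 80.0 and 36.3), although Gadd45g, a stress-induced growth arrest gene, was 2.68-fold higher at 84 h, and those of platelet and coagulation genes 0.14, 0.00 and 0.15 (92.2, 45.0 and 87.4). The T cell list had 3 members above the floor and medians of 0.06, -0.29 and -0.32 (60.0, 11.5 and 10.8). The matrix protease list did not stand apart from 36 h at any time (medians 0.07, 0.10 and 0.06; percentiles 73.5, 87.8 and 69.1), its members differing from one another, as with Mmp12 and with Mmp11, which was 2.13-fold lower at 84 h. Housekeeping genes had medians of 0.06, 0.04 and 0.06 over 36 h (65.6, 55.1 and 70.4).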

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

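The 8 probe sets below lie outside the gene comparisons, since the annotation gives them no gene or several genes, and the 4-fold range by which they were selected was chosen after the data were seen. A probe set with no gene had a range of at least 54.5-fold, its signal being 35.7, 2.6, 61.2 and 1439 intensity units at 36, 48, 60 and 84 h. A probe set shared by 4 genes ranged 7.03-fold, from 652.4 at 36 h to 4583 at 84 h. Another with no gene ranged at least 6.36-fold and was highest at 84 h (167.8).

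A probe set shared by 2 genes ranged 6.01-fold and was lower at each step (3221, 2771, 1882 and 536). Those with no gene and lowest at 84 h ranged at least 5.83-fold, 4.44-fold and 4.22-fold, with signals of 9.4, 19.5 and 14.4 at that time. A probe set shared by 5 genes ranged at least 4.11-fold and was lowest at 60 h (0.8). No explanation was tested for these probe sets.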

How the results depend on the processing

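The spike-in scaling, the counts without the adipose, erythroid and B cell lists and the peaks without the 84 h array were chosen after the data were seen. No paired analysis was possible because each time has 1 array. Of the gene counts 99 stayed within 1.5 times and 54 moved further; of the list medians 1264 stayed within 1 probe set SD, 25 moved further and 1 that had stood apart changed sign (other changes of sign, in lists that had not stood apart, are among those that moved or stayed); of the ratios of named genes 906 stayed, 148 moved and 1 changed sign, 59 of 114 moving with the floor at the 60th percentile; of the counts of list members past the threshold 2644 stayed within 1.5 times and 256 moved further. With quantile normalization, median or trimmed mean scaling, a pseudocount of 16, the mean of probe sets, or suffixed probe sets left out, all 14 gene counts stayed within 1.5 times. Values exactly as deposited are those of the report. Signals near the floor limit what can be seen, and causes were not tested except where said.

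In the order 48 over 36 h, 60 over 36 h, 84 over 36 h, 60 over 48 h and 84 over 60 h, the floor at the 25th percentile gave 96, 105, 163, 84 and 150 genes higher and 103, 124, 190, 94 and 124 lower, since by construction it admits more small signals, and 237, 155, 135 and 249 genes were highest at 36, 48, 60 and 84 h. The adipose median was then -0.20 at 60 over 36 h (0.15 in the report) and 1.31 at 84 over 36 h (0.76), the mast cell median -0.68 at 84 over 36 h (-0.35) and the neutrophil median 0.036 at 60 over 48 h (0.53).

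With the floor at the 60th percentile, which leaves fewer genes, the counts were 7, 20, 43, 9 and 32 higher and 18, 18, 50, 3 and 28 lower, and 55, 12, 26 and 60 genes were highest at the 4 times. At 48 over 36 h the mast cell median was -0.45 (-0.12 in the report). At 60 over 36 h it was 0.12 (-0.27) and the adipose median -0.26 (0.15). At 84 over 36 h the oestrogen median was -0.49 (0.08), the erythroid 0.79 (0.42) and the adipose 1.91 (0.76). The B cell median was 0.45 at 60 over 48 h (0.16). At 84 over 60 h the progesterone median was -0.10 (-0.64), the mast cell -0.70 (-0.17) and the adipose 1.36 (0.86), and the oestrogen median reversed to -0.023 (0.34).

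A 3-fold threshold, stricter by construction, gave 1, 11, 16, 5 and 16 genes higher and 4, 5, 23, 0 and 6 lower, with 24, 4, 13 and 24 highest at the 4 times. Spike-in scaling, which moved the median log2 ratio of all genes to -0.11, 0.11, -0.42, 0.23 and -0.52, gave 64 lower at 48 over 36 h, 20 higher and 360 lower at 84 over 36 h, 66 higher at 60 over 48 h, and 15 higher and 529 lower at 84 over 60 h. It put the highest value of 291, 65, 458 and 25 genes at the 4 times. Relative to the median gene, the adipose median was then 1.17 at 84 over 36 h and 1.27 at 84 over 60 h.

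With a pseudocount of 16 and no floor, the natural killer median was -0.20 at 48 over 36 h (-0.63) and -0.16 at 60 over 36 h (-0.60). The neutrophil median was 0.26 at 60 over 36 h (0.64), 0.034 at 60 over 48 h (0.53) and -0.25 at 84 over 60 h (-0.62). The T cell median was 0.031, -0.059 and -0.0069 in these comparisons (-0.29, -0.37 and -0.35), and the skeletal muscle median 0.22 at 60 over 48 h (-0.12). By construction this setting counts members that lie below the floor on both arrays. With suffixed probe sets left out, Zfp787 had a log2 ratio of -0.34 at 48 over 36 h (1.34), from another probe set of the gene. Without the 84 h array 61 genes were highest at 36 h and 23 at 48 h. Without the adipose, erythroid and B cell lists 68 genes were higher and 86 lower at 84 over 36 h.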

Other observations

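The tests of explanations in this part were chosen after the results were seen. So were the groups of chaperone, metallothionein, fatty acid and triglyceride synthesis, and clock genes. The adipose, erythroid, progesterone-regulated, structural matrix and endothelial lists were fixed before. Some chaperones of the endoplasmic reticulum, which fold secreted proteins, were higher at 84 h than at 36 h. In this group of 15 genes 5 were at least 2-fold higher and 13 above 0, with a median log2 ratio of 0.61. Hspa5, the chaperone BiP, was 3.25-fold higher (485.5 to 1576), Creld2 2.71-fold, Hsp90b1 2.31-fold, Manf 2.28-fold and Pdia6 2.10-fold. At 48 h and 60 h over 36 h the median of this group was -0.10 and 0.16. Ddit3, a stress-induced transcription factor, was 1.22-fold lower at 84 h.

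Metallothioneins, which bind zinc and copper, were lower. Mt1 was 3.25-fold lower at 84 h than at 36 h (1170 to 359.7) and Mt2 2.80-fold lower (2101 to 750.3), beside the 3.61-fold lower Slc39a4; the median log2 ratio of these 3 genes was -0.87, -0.76 and -1.70 at 48, 60 and 84 h. Some genes of fatty acid and triglyceride synthesis were higher at 84 h, with a median of 1.12. Of 8 genes 5 were at least 2-fold higher, Scd1 by 6.84-fold, Gpd1 by 2.37-fold, Me1 by 2.35-fold, Elovl6 by 2.21-fold and Thrsp by 2.13-fold. Adipocytes express such genes abundantly, and the adipose list was higher at the same time (median 0.76, percentile 100).

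Some genes of fat and blood were higher at 84 h, where 5 of 10 adipose and 2 of 6 erythroid list members passed 2-fold. Array scaling as the whole cause is argued against, since 1 factor moves all genes of an array alike. The list medians lay 0.75 (adipose, 0.10 to 3.26 over resampled members) and 0.42 (erythroid, 0.058 to 2.76) above the median of all genes on the log2 scale. These differences restate the list medians and are no separate support, and 5 of the 10 adipose members, at the floor at 36 h, could only come out higher. Fat carried along with the uterine horn stays open: without the members named for their own ratio, the 6 other adipose members lay at percentile 96.2, and the levels at 84 h were 893.5 for Car3, 603.8 for Adipoq, 385.1 for Lpl and 253.5 for Retn, with Fabp4 at 55.5 and Cidec at 35.2; 5 of the 10 lay above the floor at 36 h and 0 are in another list. Blood in the 84 h tissue stays open too, the 4 other erythroid members lying at percentile 83.6, with Hba-a1 at 3946; 5 of the 6 lay above the floor at 36 h and 0 are in another list. With 1 pool per time neither can be told apart from more fat cells or bleeding in the uterus itself, which was not tested.

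Some progesterone-regulated genes were lower at 84 h, 7 of 17 by at least 2-fold, while 9 were within 2-fold and 1, Pgr, was higher. Dilution of uterine RNA by fat and blood cannot be told apart from a change in these genes. The structural matrix median lay 0.67 and the endothelial median 0.73 above theirs, and the cell cycle median was 0.10 (18 of 29 above 0). These values speak against dilution, whereas the smooth muscle, epithelial and decidual stroma medians were also low (-0.53, -0.27 and -0.23), which dilution would give. Resampled members gave -0.12 to 1.26 for the matrix difference, and fat itself holds matrix and vessels. The median of the progesterone-regulated genes was already -0.24 and -0.29 at 48 and 60 h, where that of the adipose list was -0.06 and 0.15. These adipose medians rest on 5 and 6 members, and that of 60 h was -0.20 with the lower and -0.26 with the higher floor. Loss of RNA integrity in the later pools stays open as well. The 3' to 5' ratio rose by over 1.1 times from 36 h to 84 h in 2 of 3 control genes (1.37 times for actin, 1.34 times for pyruvate carboxylase, 1.01 times for Gapdh). That of actin was highest at 84 h (1.76), but that of pyruvate carboxylase was highest at 48 h (4.32) and was 2.90 at 60 h. An effect of progesterone withdrawal or of time is the biological explanation that the design names, and it was not tested separately.

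Some clock output genes were higher at 48 h: Dbp was 73.7, 178.4, 77.1 and 45.2 in time order, Nr1d1 58.3, 104.4, 53 and 60.8, and Nr1d2 88.4, 193.3, 120.6 and 129.6, and Arntl was lowest at 48 h (34.1). Of 5 such genes 2 were at least 2-fold higher at 48 h than at 36 h and 3 above 0, while Tef was 1.11-fold lower (285.1 to 257.6) and Per3 was at 67.4 at both times; Nfil3 was lowest at 84 h (31.7). A time of day of collection 12 h apart from that of the other arrays may be the source, since 36, 60 and 84 h lie whole days apart. Of 7 clock genes 4 were extreme at 48 h in the sense this predicts, and 2 of the 5 that were under 2-fold apart, where chance gives 25%, so that the test leaves it open; Per1, a clock gene not among the 7, was 74.5, 34.5, 53.2 and 31.8 and so not extreme at 48 h. Whether the clock genes follow the hormone instead was not tested.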
